A study of Homo sapiens with 6 samples.

How the data were processed

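RNA from 6 samples of N/TERT-1 cells, a human keratinocyte line immortalised with telomerase, was measured on 1-colour Illumina bead arrays. Per the labels, 3 samples had received a negative control mimic and 3 a miR-335 mimic, a synthetic RNA that stands in for the mature microRNA. Total RNA was taken 48 h after transfection and biotin-labelled cRNA was hybridised. The dose is given as 20 nM in the labels' treatment protocol and as 30 nM in the series design, and the files do not settle which was used. The medium held 0.2 ng/mL EGF, 25 µg/mL bovine pituitary extract and 0.4 mM CaCl2, per the labels' growth protocol. The labels number the replicates 1 to 3 in each group without saying whether they were separate cultures or separate days. The p-values below therefore measure only the spread between these samples, which may be technical. The labels do not say which arm of miR-335 the mimic carried.

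The authors deposited a table of probe intensity values that were not normalized between arrays, with a detection value for each probe and array. Between 25.9% and 27.5% of the intensities of an array lay below 0, as background-subtracted values do. The deposited detection column rose with the signal on every array (lowest rank correlation 0.916), so it holds 1 minus a detection p-value, and the detection p used here was 1 minus the deposited number. The authors also deposited a normalized table of linear intensities. The median of the largest difference between its sorted columns was 0, as after quantile normalization, and its column medians lay between 16.8 and 16.9. GenomeStudio 1.9.0 is named in the submitters' processing notes. The method of background subtraction and of normalization is not given in the sources used here.

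The non-normalized table identifies probes only by array address, and the normalized table only by Illumina probe ID. With no probe column in common, probes were paired by their ranks on all 6 arrays, which quantile normalization leaves nearly as they were. All 47323 probes of one table paired one to one with the 47323 of the other. The median distance was 0.00304 to the partner and 0.268 to the next nearest probe. After pairing, 99.2% of probes had all 6 values within 0.5 intensity units of those that quantile normalization of the first table predicts. Swapping any pair of columns (15 swaps) raised the median distance to at least 0.215. The gene name of every value from the non-normalized table rests on this pairing. The values and names of the normalized table do not need it, and that table was run as an alternative, with the detection filter still taken through the pairing.

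Gene names came from the platform's annotation, updated through the Entrez gene identifier where that changed a symbol (0 probes). Of the 47323 probes, 30113 had 1 gene, 8 had several and 17202 were unnamed here. Probes were kept if their detection p was under 0.05 on at least 3 of the 6 arrays, which left 21062 probes, 16033 of them with 1 gene. A gene took the kept probe with the highest mean over the 6 arrays, which gave 11909 genes. Genes with no named probe were not analysed here. No coordinates are given, because the genome build behind the annotation is not stated.

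Signals were background-corrected with normexp from the detection p-values (offset 16), quantile-normalized and log2-transformed with limma's neqc function. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, both directions tested), with Benjamini-Hochberg adjustment over all 21062 kept probes and a threshold of 0.05 on adjusted p. Every adjusted p of a gene comes from that fit. Log2 changes are mimic minus control, with their standard error. They are on a scale with an offset of 16, which understates the change of dim genes. Where a probe was not detected on any array of one group, its change is given only as "at least N-fold". That bound sets the brighter group's mean against the dimmer group's mean after each dim array was raised to the lowest signal among probes detected on it. Python 3.11.15 with scipy 1.17.1, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used to pair the probes and to draw the plots.

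A total of 28 gene lists was fixed before the data were examined, as were the group assignment, the design, most of the alternative settings and the rule for the genes named. The lists hold 784 symbols, of which 737 had a probe and 607 were tested. They cover the cornified envelope, suprabasal and basal keratinocytes, the epidermal lipid barrier, epidermal proteases and inhibitors, keratinocyte differentiation regulators, desmosomes, tight and adherens junctions, DNA replication, mitosis, the type I interferon response, cytokines and chemokines, stress keratins and antimicrobial proteins, genes reported as miR-335 targets in other cells, the SWI/SNF complex, histone deacetylases, small RNA machinery, cholesterol biosynthesis, EGFR and ERK feedback, the Notch pathway, the TGF-beta response and mesenchymal genes, p53 targets, the unfolded protein and integrated stress response, hypoxia, fibroblast, immune cell and melanocyte markers, and housekeeping genes. Lists with at least 5 measured genes were tested with limma's camera (preset inter-gene correlation 0.01), adjusted over the 27 lists tested. Camera asks whether a list's genes shifted relative to the other genes. An estimated correlation and limma's fry were alternatives. Some genes stand on more than 1 list.

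The genes named are the 10 largest rises and 10 largest falls among genes past the threshold whose 3 mimic arrays all lay on one side of the 3 control arrays, SOX6 and MEST, up to 4 members with the largest change among those past the threshold in each list (up to 2 where fewer than 2 passed), and the reported miR-335 targets past the threshold. Genes outside that rule were named after their values were seen, either because a count was 5 or fewer or because they belong to gene families picked from the results.

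The fit was tested on simulated arrays with the mean and spread of the 21062 kept probes and 200 changed probes, 50 at each size. It recovered 12% of changes of 1.25-fold, 46% of 1.5-fold, 74% of 2-fold and 92% of 3-fold, with 7 false calls among 119. With no change simulated it called 0 probes and 0 lists. Probes were simulated independently of each other, and far fewer changed than were called in the data, so these shares describe the simulation only. The number of arrays limits the precision.

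The alternative settings were no background correction, the authors' normalized table, median scaling, cyclic loess, an offset of 50, no filter on dim probes, detection p under 0.01 on all 6 arrays, an intensity trend with a robust prior, array weights, the mean of all kept probes of a gene, the replicate number as a block, a test against a 1.2-fold change, and leaving out each array in turn with the probe filter kept from all 6 arrays. A block on the slide, also set out, was not run because the files used here do not give the slide. A search for miR-335 seed matches, set out in the design, was not run because no 3′ UTR sequences were used here. The filter of detection p under 0.01 on all 6 arrays was applied to gene families after the data were seen. MEST was not detected, so its only value under these settings is the one with no filter.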

Results

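Gene expression was measured in N/TERT-1 keratinocytes transfected with a miR-335 mimic (n = 3 arrays) or a negative control mimic (n = 3 arrays). The design addresses which transcripts change when miR-335 is raised in these cells, with keratinocyte differentiation as the stated interest of the series. Between 20452 and 21476 of 47323 probes were detected per array (43.2% to 45.4%), and the mean signal per array lay between 670.3 and 720.5 intensity units. Correlations of log2 values across probes were 0.9936 to 0.9946 between arrays of one group and 0.9891 to 0.9903 between arrays of different groups. The first principal component held 44.5% of the variance, with the control arrays at -20.13 to -17.46 and the mimic arrays at 18.89 to 19.37.

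The miR-335 mimic lowered SOX6, a transcription factor gene and reported miR-335 target, more than any other gene that passed the threshold and was detected in both groups. SOX6 fell 3.22-fold, from a log2 level of 8.52 ± 0.19 to 6.84 ± 0.13 (mean ± SD, n = 3 each; log2 change -1.69, SE 0.12, limma adjusted p = 0.00195). Its lead over GBP4 (-1.62) and KMO (-1.56) was small. One of these genes fell more than SOX6 without control array 1 or 3 or mimic array 1 or 2. With the mimic, the lists of the cornified envelope, of stress keratins and antimicrobial proteins, of DNA replication and of mitosis shifted up. The list of type I interferon response genes shifted down. Many envelope risers were small proline-rich (SPRR) genes, some with probes that can read each other's transcripts. The measured stress keratins did not pass. Among genes detected in both groups the largest rise was that of IL24, a cytokine of the IL-10 family, at 4.12-fold (log2 change 2.04, SE 0.09, adjusted p = 0.000676).

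In all, 1604 of 11909 genes changed (13.5%), of which 760 rose and 844 fell. The changes were mostly small, with a median absolute log2 change of 0.43. At least 1.5-fold changes were seen in 195 genes that rose and 198 that fell, and at least 2-fold changes in 37 and 34. Over all 11909 genes tested, called or not, the 3 mimic arrays lay on one side of the 3 control arrays in 40.3%, where chance alone gives 10%. Counted by probe, 2408 of 21062 passed, 1175 up and 1233 down, including 340 of the 5029 kept probes with no gene name here. At an unadjusted p under 0.05 the number of probes was 6036. Of the 461 genes called with more than 1 kept probe, 157 had the same call from all of them and 63 had a kept probe with a change of opposite sign. Among genes named by the rule, DEFB103A, SMPD1, JUP, NECTIN1, HDAC9, TNRC6A, MSMO1, NUMB, TAGLN and CD68 had a kept probe that did not pass. The count depended on every array. It was 894, 638 and 790 without control array 1, 2 or 3, and 544, 512 and 550 without mimic array 1, 2 or 3. It was also 623 with no filter on dim probes and 475 with the replicate number as a block. An intensity trend with a robust prior gave 3015, and a test against a 1.2-fold change gave 191.

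SOX6 had 4 probes on the array. The brighter detected one gave the value above, and the other detected probe fell by 2.00 on the log2 scale (SE 0.10, 3.99-fold, adjusted p = 0.000938). The remaining probes of SOX6 were below the detection filter and were not tested. On the brighter probe the control arrays read 8.67, 8.31 and 8.59 and the mimic arrays 6.69, 6.88 and 6.95. The 3 probes of MEST, the gene whose intron encodes miR-335, were detected on 0 of the 6 arrays, so no level is given for it. Among 14 measured genes reported as miR-335 targets in other cells, SOX6 fell and TNC, which encodes the matrix protein tenascin-C, rose (log2 change 0.40, SE 0.06, adjusted p = 0.0117), and 12 did not pass. Adjusted over the list alone, 1 rose and 2 fell. The list test did not call the reported targets as a group (camera adjusted p = 0.995). TNC was called in 4 of the 6 fits that left out 1 array, missing without mimic array 1 or 3. The median of the list, 0.03, and its mean, -0.09, differ in sign.

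By fitted change, the 10 genes with the largest rises were IL24, SCG5 (log2 change 1.67), SPRR2A (1.56), the envelope cross-linking enzyme TGM1 (1.55), the calgranulin S100A12 (1.43), the stromelysin MMP10 (1.42), the keratin KRT24 (1.37) and 3 genes known only by a bound. These were DEFB4A, which encodes beta-defensin 2 (at least 2.33-fold), the imprinted long non-coding RNA H19 (at least 2.55-fold) and the hyaluronan synthase HAS2 (at least 2.79-fold). They were not detected on any control array and were detected on all 3 mimic arrays, so they have no rank against the others. After SOX6, the largest falls among genes detected in both groups were those of the interferon-inducible GTPase GBP4 (-1.62), the kynurenine pathway enzyme KMO (-1.56), the ubiquitin ligase component FBXO32 (-1.49), DEPP1 (-1.44), the phospholipase and acyltransferase genes PLAAT3 (-1.39) and PLAAT2 (-1.29), the neuroserpin gene SERPINI1 (-1.35), the histone gene H2AC18 (-1.34) and RTP4 (-1.29). Adjusted p-values of these 20 genes lay between 0.000637 and 0.00617, and all 20 were called in each of the 6 fits that left out 1 array.

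**Figure D1:**
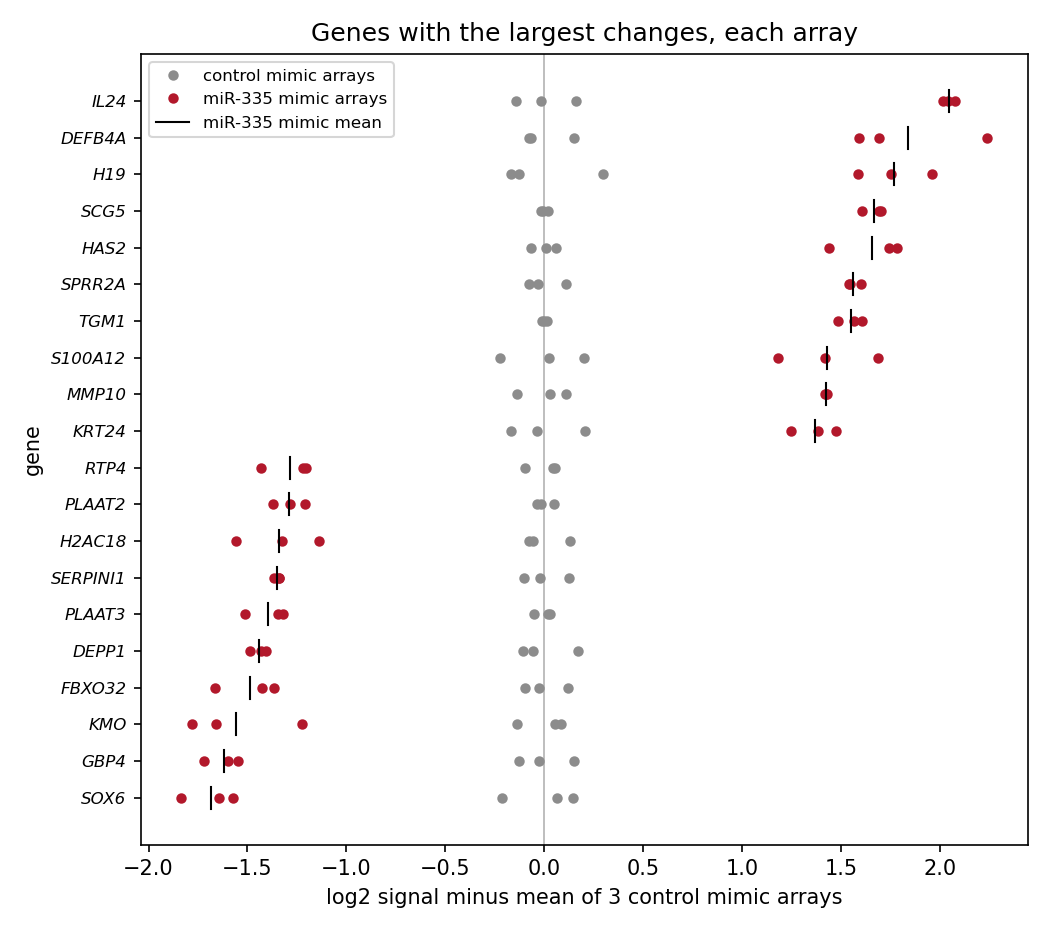
Log2 signal of each array (x axis, minus the mean of the 3 control arrays) for the 10 genes with the largest fitted rise and the 10 with the largest fitted fall (y axis). Grey points are control mimic arrays, red points miR-335 mimic arrays and the black line the mean of the 3 mimic arrays. The rule that picked these genes required the 3 mimic arrays to lie apart from the 3 control arrays. Mean changes run from 2.04 for IL24 to -1.69 for SOX6. DEFB4A, H19 and HAS2 were below detection on the control arrays, so their plotted changes and their places in the order are not exact.

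Cornified envelope genes, which encode the proteins cross-linked beneath the membrane of the outermost keratinocytes, moved in both directions. Of 26 measured, 12 rose, 4 fell and 10 did not pass (14 and 4 adjusted over the list alone). Risers included SPRR2A (log2 change 1.56, SE 0.07), TGM1 (1.55, SE 0.06) and SPRR2F (1.16, SE 0.07). With them rose a further 6 small proline-rich genes and, named after their values were seen, IVL, which encodes involucrin, TGM3 and CNFN. The genes that fell were RPTN, which encodes repetin (at least 1.61-fold), and, named after their values were seen, FLG, which encodes profilaggrin (at least 1.59-fold), CRNN, which encodes cornulin (at least 1.19-fold), and LCE1B (log2 change -0.64). RPTN, FLG and CRNN were detected on all 3 control arrays and on none of the mimic arrays. The list as a whole shifted up (median 0.52, camera adjusted p = 4.07e-05, and adjusted p = 0.0461 with an estimated correlation). With no filter on dim probes, which adds undetected members, the median was 0.10 and the camera adjusted p 0.000265. Probes of the near-identical SPRR2 genes can read each other's transcripts, so single members of that family are uncertain. The number of envelope genes that rose and the list test may therefore count a transcript more than once. No list test without that family was run.

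Genes of the suprabasal, differentiating layers rose in 13 of 27 measured cases, with 0 falls and 14 not passing (15 rose and 1 fell adjusted over the list alone). They included KRT4 (0.82), NOTCH3 (0.72), KRTDAP (0.68) and the mucosal keratin KRT13 (0.59). The shift of the list (median 0.40, camera adjusted p = 1.25e-06) was lost with an estimated correlation (adjusted p = 0.0584), and leaving out any 1 of the 6 arrays lowered the number that rose to between 5 and 8. KRT4 and NOTCH3 were each called in 2 of those 6 fits. Stress keratins and antimicrobial proteins, markers of wounded or inflamed epidermis, rose in 16 of 20 cases with 0 falls (16 and 0 adjusted over the list alone). Among them were S100A12 (1.43), the protease inhibitor SLPI (1.14), the beta-defensin gene DEFB103A (1.09) and DEFB4A, known only by its bound (at least 2.33-fold). The measured stress keratins of the list, KRT6C (0.30, adjusted p = 0.166) and KRT16 (0.18, adjusted p = 0.206), did not pass, so the rises were those of its other members. This list had the highest median of those tested (0.72, camera adjusted p = 4.2e-13, and adjusted p = 0.0403 with an estimated correlation). Of cytokines and chemokines, 9 of 21 rose, 1 fell and 11 did not pass (13 and 2 adjusted over the list alone). IL24 (2.04), the neutrophil chemokine CXCL8 (0.86), IL36G (0.79) and IL6 (0.77) led the rises, and TNF, named after its value was seen, fell (-0.62). The list shifted up (median 0.27, or 0.16 with no filter on dim probes, camera adjusted p = 0.000109, and adjusted p = 0.0461 with an estimated correlation), and 5 of its genes rose without mimic array 1. IL6 was called in 2 of the 6 fits that left out 1 array.

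Genes of the cell cycle rose by small amounts. In the DNA replication list 24 of 43 measured genes rose and 0 fell (33 and 0 adjusted over the list alone), among them the checkpoint gene CLSPN (0.63), RAD51AP1 (0.56), the helicase subunit MCM4 (0.48) and the primase subunit PRIM1 (0.47). The median was 0.31 (camera adjusted p = 4.2e-13, and adjusted p = 0.0134 with an estimated correlation). In the mitosis list 16 of 55 rose and 0 fell (39 and 0 adjusted over the list alone), among them CCNA2 (0.47), which encodes cyclin A2, the kinases AURKB (0.44) and BUB1 (0.44) and the phosphatase CDC25C (0.42). The median was 0.25 (camera adjusted p = 4.67e-12, and adjusted p = 0.0134 with an estimated correlation). These counts rested on the full set of arrays: leaving out any 1 of the 6 lowered the number that rose to between 3 and 11 for DNA replication and to between 0 and 5 for mitosis, while both list shifts stayed past the threshold. RAD51AP1 and PRIM1 were called in all 6 of those fits, AURKB in 3, CLSPN and BUB1 in 2, MCM4 and CCNA2 in 1 and CDC25C in 0. Another kept probe of CDC25C had a change of opposite sign.

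Type I interferon response genes fell in 20 of 51 measured cases, 1 rose and 30 did not pass (30 fell and 2 rose adjusted over the list alone). The antiviral genes IFIT2 (log2 change -0.92, SE 0.07) and RSAD2 (-0.79, SE 0.08) and the GTPase gene GBP1 (-0.80, SE 0.07) fell most. IFNK, which encodes the keratinocyte interferon kappa, went the other way and rose at least 1.80-fold, from no detection on the control arrays to detection on all 3 mimic arrays. The list shifted down (median -0.22, camera adjusted p = 1.06e-09, and adjusted p = 0.0134 with an estimated correlation). Without any 1 of the 6 arrays, between 9 and 13 of its genes fell, and IFNK was called in 2 of those 6 fits.

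The unfolded protein and integrated stress response and the hypoxia response were also called, with small medians. In the former 7 of 24 genes rose and 0 fell (8 and 0 adjusted over the list alone). They included the amino acid and stress response genes ASNS (0.70), TRIB3 (0.68), XBP1 (0.58) and PHGDH (0.56). The median was 0.11 (camera adjusted p = 0.00331), and the call was lost with an estimated correlation (adjusted p = 0.0804). Without control array 2 or 3 or any mimic array, 4 of its genes rose. In the hypoxia list 9 of 26 genes rose and 1 fell (10 and 1 adjusted over the list alone). ANGPTL4 (0.88), PFKFB4 (0.60), NDRG1 (0.59) and LOX (at least 1.32-fold) rose, and ADM, named after its value was seen, fell (-0.33). The median was 0.08 (camera adjusted p = 0.00112), and this call too was lost with an estimated correlation (adjusted p = 0.0584). The estimates were 0.00524 for the unfolded protein and integrated stress response and -0.0195 for hypoxia, below the preset 0.01. A higher correlation was therefore not what lost these calls. Without 1 array, between 3 and 6 of the hypoxia genes rose and 0 fell, so ADM was called in 0 of those fits. Another kept probe of ANGPTL4 had a change of opposite sign. XBP1 was called in 2 and LOX in 1 of the 6 fits that left out an array.

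**Figure D2:**
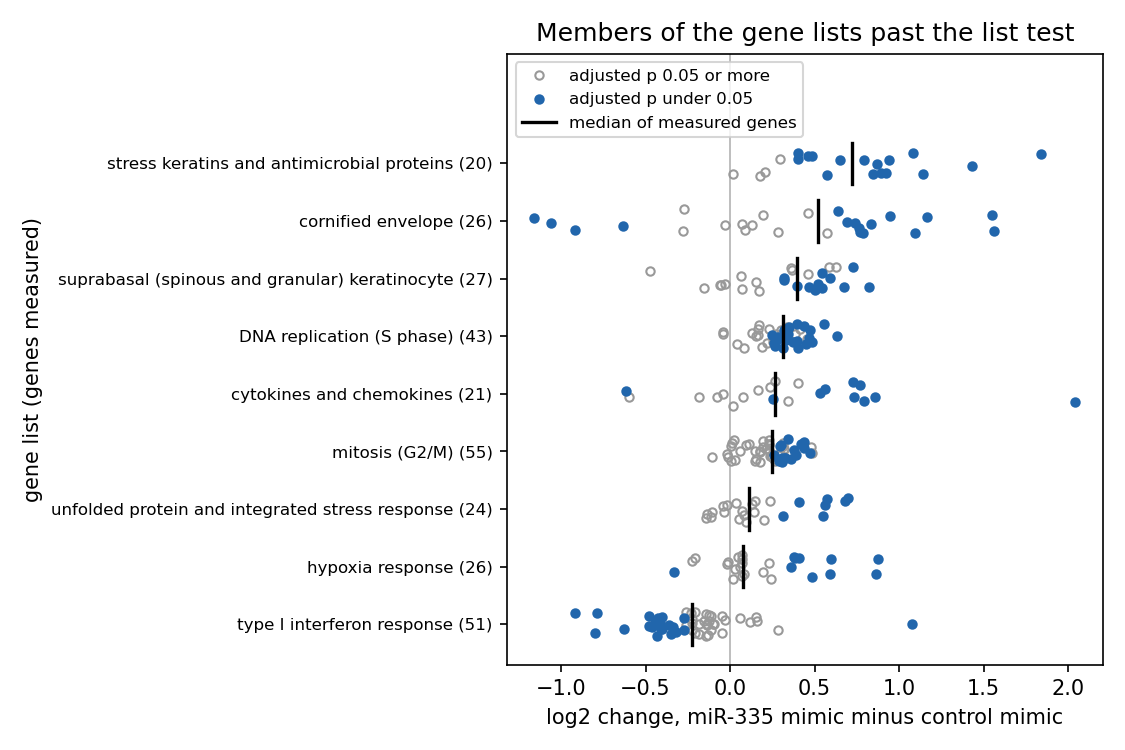
Log2 change of each measured gene (x axis, miR-335 mimic minus control mimic) in the 9 gene lists past the camera test (y axis, with the number of genes measured). Filled points are genes with a limma adjusted p under 0.05, open points the others, and the black line is the list median, from 0.72 for stress keratins and antimicrobial proteins to -0.22 for the type I interferon response. Cornified envelope genes lie on both sides of 0, and 1 interferon list gene, IFNK, lies far to the right of the others.

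The list test did not call the other 18 lists. Epidermal proteases and inhibitors had 9 of 24 rise and 4 fall (10 and 7 adjusted over the list alone, camera adjusted p = 0.161, and 0.0159 with no filter on dim probes). SLPI (1.14), SERPINB4 (0.94), ASPRV1 (0.90) and KLK11 (0.90) rose most, and SERPINB13, PRSS8, KLK9 and ST14, named after their values were seen, fell. Without 1 array between 4 and 7 of these genes rose and 2 or 3 fell, with ASPRV1 called in 2 and SERPINB4 in 1 of the 6 fits. Of the TGF-beta response and mesenchymal genes, 5 of 20 rose and 7 fell (7 and 8 adjusted over the list alone, camera adjusted p = 0.995). FN1 (-0.79), which encodes fibronectin, TAGLN (-0.64) and CCN1 (-0.59) fell and TGFBI (0.75) rose, as did TNC and, named after their values were seen, LTBP2, VIM and ACTA2. The median of this list was 0.08 and its mean -0.02, so they differ in sign. Without 1 array between 2 and 4 of these genes rose and between 4 and 6 fell. Of the EGFR and ERK feedback genes, 5 of 28 rose and 4 fell (10 and 4 adjusted over the list alone, camera adjusted p = 0.334). MMP10 (1.42), MMP9 (0.98) and EREG (0.61), and after their values were seen TGFA and PHLDA1, rose, and EGR1 (-0.84), and after their values were seen SPRY1, CCND1 and PLAUR, fell. Another kept probe of PLAUR had a change of opposite sign. Without 1 array between 1 and 3 of these genes fell.

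Basal keratinocyte genes moved little. Of 26 measured, 2 rose and 2 fell (5 and 2 adjusted over the list alone, camera adjusted p = 0.283). The basal keratin KRT15 (-0.71) and ITGA5 (-0.28) fell, and COL7A1 (0.56) and PDPN (0.53) rose. Of the keratinocyte differentiation regulators 1 of 27 rose, HOPX (0.59), and 1 fell, GATA3 (-0.39) (1 and 1 adjusted over the list alone, camera adjusted p = 0.612). Of the epidermal lipid barrier genes 1 of 17 rose, SULT2B1 (0.99), and 1 fell, SMPD1 (-0.57) (1 and 1 adjusted over the list alone, camera adjusted p = 0.877). Among junction genes, JUP (-0.54), which encodes plakoglobin, was the only 1 of 15 desmosome genes to fall and none rose (2 fell and 1 rose adjusted over the list alone, camera adjusted p = 0.44), with DSG1 at 0.36 not passing. Of 18 tight and adherens junction genes CGN (-1.12), which encodes cingulin, fell and NECTIN1 (0.63) rose (1 and 1 adjusted over the list alone, camera adjusted p = 0.317). When each array was left out in turn, HOPX was called in 4 of the 6 fits, NECTIN1 in 2, PDPN in 1, and GATA3 and ITGA5 in 0, and the other genes of this paragraph past the threshold in all 6.

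Among regulators of chromatin and RNA, the SWI/SNF ATPase gene SMARCA2 fell (-0.71) and PHF10 rose (0.40) out of 24 genes (1 and 1 adjusted over the list alone, camera adjusted p = 0.44). The deacetylase genes HDAC9 (-0.46) and HDAC4 (-0.28) fell out of 15 and 0 rose (2 and 0 adjusted over the list alone, camera adjusted p = 0.0814). The deacetylase list passed the test without control array 2 (camera adjusted p = 0.0493), without mimic array 1 (0.0366), with no filter on dim probes (0.0308) and with the mean of all probes of a gene (0.0428). Of 12 small RNA machinery genes TNRC6A (0.33) rose and AGO1 (-0.31) fell (1 and 1 adjusted over the list alone, camera adjusted p = 0.676). Of 21 cholesterol biosynthesis genes MSMO1 (-0.50), TM7SF2 (-0.40) and LSS (-0.28) fell and FDPS (0.31) rose (4 fell and 1 rose adjusted over the list alone, camera adjusted p = 0.396). Of 20 Notch pathway genes LFNG (-0.44), HES2 (-0.32) and NUMB (-0.28) fell and NOTCH3 (0.72) rose (3 fell and 4 rose adjusted over the list alone, camera adjusted p = 0.676). Of 24 p53 targets TP53I3 (-0.53), CDKN1A (-0.35) and PPM1D (-0.35) fell and DDB2 (0.34) rose (4 fell and 2 rose adjusted over the list alone, camera adjusted p = 0.995). LSS, TP53I3 and CDKN1A each had another kept probe with a change of opposite sign. SMARCA2, MSMO1 and TP53I3 were called in all 6 fits that left out 1 array, TM7SF2 in 4, NOTCH3 and CDKN1A in 2, PHF10, HDAC9, LFNG and PPM1D in 1 and the rest in 0.

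The marker lists of other cells and the housekeeping genes gave single calls. Of 6 measured fibroblast markers COL5A2 (-0.81) fell and 0 rose (2 and 0 adjusted over the list alone, camera adjusted p = 0.45), with S100A4 at 0.46 not passing. Of 7 immune cell markers CD68 (0.39) rose and 0 fell (1 and 0 adjusted over the list alone, camera adjusted p = 0.995), with CD2 at -0.40 not passing. Fewer than 5 melanocyte markers were measured, and that list was not tested. Of 17 housekeeping genes POLR2A (-0.26) fell and 0 rose (0 and 0 adjusted over the list alone, camera adjusted p = 0.161), with SDHA at 0.29 not passing. COL5A2 was called in all 6 fits that left out 1 array, and CD68 and POLR2A in 0.

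Of the 9 list shifts, 8 up and 1 down, 6 held with an estimated correlation.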

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

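The signs of the 20 genes with the largest changes and their calls were kept under every alternative that tested them, and SOX6 ranged from -1.84 to -1.44. Log2 changes from the authors' normalized table correlated with those reported at r = 0.991 across probes (0.999 with detection p under 0.01 on all 6 arrays). The tables were paired by the closeness of their values, so much of this agreement was built in. It cannot test the pairing. Against 1604 genes (760 up, 844 down), no filter on dim probes gave 623 (303 and 320), with more probes sharing the adjustment. An intensity trend with a robust prior gave 3015 (1439 and 1576) and the strict filter 2378, for which the cause was not tested. Testing against a 1.2-fold change gave 191 (85 and 106, of which 82 and 106 reached 1.5-fold), a stricter question by construction. An offset of 50, which shrinks changes by construction, left 18 up and 22 down at 2-fold and 126 and 127 at 1.5-fold, and the strict filter, which removes genes undetected in one group, left 22 up at 2-fold. Leaving out 1 array gave 512 to 894 genes (231 to 432 up, 281 to 462 down), with fewer samples. The replicate number as a block gave 475 (226 and 249), and the number of lists called stayed at 9. Deviations of same-numbered arrays correlated at 0.085, 0.001 and 0.043, and those of other pairs across groups at -0.072 to 0.032. The labels do not say what arrays of one number shared, so a batch by number stays open. Median scaling called 53.2% of its genes up, against 47.4%. Fry, which asks if a list moves at all, called 18 lists against 9. LSS turned from -0.28 to 0.01 with the mean of its probes, whose cause was not tested. Of the other tests of named genes, 1416 gave the same call, 291 the same sign without the call and 6 a gained call (all SDHA). Of the 9 list calls, 3 were lost, each only with an estimated correlation. Unfiltered, MEST read 0.17 (adjusted p = 0.758). Signal over background limits the genes undetected in one group, whose changes are bounds.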

Other observations

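Apart from the counts over other splits of the arrays, the tests and gene families in this part were chosen after the results were seen, and the criteria for every test were written after its value was known.

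The SPRR and PLAAT families each moved in one direction, and the S100 and GBP families only in part. All 9 measured small proline-rich (SPRR) genes rose, with a median log2 change of 0.95, including SPRR2C (1.33) and SPRR2E (1.09). Since SPRR2 probes can read each other's transcripts, these rises may not be separate. All 3 measured PLAAT genes, which encode phospholipase A and acyltransferase enzymes, fell, with PLAAT4 at -0.99 beside PLAAT3 and PLAAT2. Among 16 measured S100 calcium-binding genes 8 rose and 0 fell, the largest after S100A12 being S100P (0.93), S100A9 (0.87) and S100A8 (0.84), while the abundant S100A10 (-0.01), S100A6 (-0.04) and S100A11 (-0.10) did not pass. Without 1 array, 5 or 6 of the S100 genes rose. Of 6 guanylate-binding protein genes GBP4 (-1.62), GBP1 (-0.80), GBP2 (-0.60) and GBP3 (-0.31) fell, GBP6 (-0.25) did not pass and GBP5 rose (1.18, SE 0.12, adjusted p = 0.00438). GBP3 was at the threshold (adjusted p = 0.0497), and 3 of these genes fell in each fit that left out 1 array.

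Keratin genes were split. Of 15 measured, 6 rose, led by KRT24 (1.37), KRT34 (1.00) and KRT23 (0.89), and 2 fell, the simple epithelial keratin KRT8 (-1.03) and the basal keratin KRT15 (-0.71). The main basal keratins KRT5 (0.04) and KRT14 (0.06) and the stress keratin KRT16 (0.18) did not pass. Between 4 and 6 keratin genes rose, and 2 fell, when 1 array was left out.

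Replication-dependent histone genes, which cells transcribe mostly in S phase, fell in 13 of 27 measured cases and rose in 2, with a median of -0.498, while DNA replication genes rose. Whether these probes read all histone transcripts or only those with a poly(A) tail was not tested. Only 27 of the 88 family members passed the detection filter, and the median was -0.08 with no filter and -0.764 with detection p under 0.01 on all 6 arrays. H2AC18 (-1.34), H2AC21 (-1.25) and H2BC21 (-1.19) fell most and H2BC9 (0.75) and H4C12 (0.45) rose, and of 11 replacement histone genes 2 rose and 1 fell. With 1 array left out, 11 to 13 replication-dependent genes fell and 1 or 2 rose, and 0 replacement genes rose in any of the 6 fits.

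The rise of the DNA replication list (median 0.313) is part of the pattern described above. That list was fixed before the data were examined. Of its 43 measured genes 24 rose and 0 fell, and its lowest median with an array left out was 0.302. In the mitosis list 16 of 55 measured genes rose and 0 fell. Fewer cells in S phase would lower the DNA replication genes too. These values therefore argue against it as the whole cause of the lower histone genes. The share of cells in S phase was not measured by these arrays. Genes outside the family, sorted into 20 bins by level, had a lowest median of -0.027 in the 13 bins that hold measured family members. The highest was 0.008. Quantile normalization itself holds such medians near 0. Genes at these levels thus shared no shift near the histone median of -0.498, which argues against a trend with intensity left by normalization as the whole cause. With median scaling instead, the histone median was -0.48. The bins replaced a test with random gene lists, dropped after its result was seen because the family was picked for its fall. Probes of near-identical histone genes reading a shared transcript stay open, since the deviations of the 13 fallen probes correlated at a median r of -0.11 but probes of one gene reached only 0.117, too low a benchmark to decide. An effect of miR-335 on these genes was not tested apart from these and stays open.

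The fall of the type I interferon response genes was spread over the arrays. The highest list median with 1 array left out was -0.194, which argues against a single unusual array, and the list level averaged 12.48 to 12.49 on the control arrays and 12.26 to 12.27 on the mimic arrays. The cytokine list median of 0.265 argues against a fall of all innate response genes. A response to the control mimic that the miR-335 mimic raised less and a fall caused by miR-335 cannot be told apart, since 0 untransfected arrays were analysed here.

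Within the cornified envelope, SPRR genes rose while genes of the S100 fused-type family, whose proteins include filaggrin, fell: RPTN, FLG and CRNN among 4 measured, with TCHH (-0.28) not passing. With the 3 undetected genes set at their bounds, the S100 fused-type median was -0.47, against 0.95 for SPRR, and no test of that difference is given because the families were picked for it. The fitted S100 fused-type median ran from -1.501 with no background correction to -0.275 with no filter on dim probes.

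All 4 fallen envelope genes (with LCE1B) were called in all 6 fits that left out 1 array, which argues against a single noisy array near background. Outside the SPRR family 4 envelope genes rose, so cross-hybridisation within that family does not account for every riser. The 4 fallen genes also lie outside it, so a rise of the envelope genes apart from SPRR is not shown. That array test replaced an earlier one, dropped after its result was seen, which asked for detection p under 0.01 on all 6 arrays: 0 of the 4 genes met it, LCE1B included, so it tested none of them. A split of the envelope program by miR-335 may be considered as a hypothesis only, because 3 of the 4 falls are known just as bounds.

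The split of the arrays by treatment called 1604 genes, and the highest of the other splits into 3 and 3 called 0. For lists the counts were 9 and 6. In both cases 1 of the 10 splits, the real one, reached the real count, and 10 splits are too few for a share under 0.05. Each of the other splits puts arrays of both treatments on both sides and still keeps part of the treatment difference, so their list counts are not those of unchanged arrays. Simulated arrays with no change, with genes drawn independently, gave 0 lists.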
